A study of Mus musculus with 6 samples.

How the data were processed

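Total RNA of E14 cells, a mouse embryonic stem cell line grown without feeder cells in serum and LIF, was measured on 6 Illumina bead arrays. Per the labels' protocols, total RNA was turned into biotin-labelled cRNA before hybridisation. Each array gave 1 value for each of 45281 probes. Of the 6 samples, 3 had been transfected with a scrambled shRNA and 3 with an shRNA against Ncoa3, all taken at day 4, and the labels call the 3 samples of each group biological replicates. Group and replicate number were taken from the sample titles.

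The deposited signal table held probe intensity on a linear scale, which the authors left non-normalized per the file headers. It was not background-subtracted, since its lowest values lay between 45.0 and 54.2 and none was below 0. Beside each intensity the deposited table gave a detection p-value, the share of negative control beads that were brighter than the probe, in steps that correspond to 928 to 930 negative controls. Control probes themselves and the scanning software were not given in the sources used here. The authors' normalized values, a second deposited table, were also on a linear intensity scale. Set against the raw signal, each of its columns kept the order of all probes exactly (rank correlation 1), and the column of the third knockdown array equalled the raw signal (largest difference 0). Its column medians were 92.7, 93.5 and 92.4 for scrambled replicates 1 to 3, and 89.4, 88.4 and 87.6 for knockdown replicates 1 to 3. The scale of those values was therefore known, while the method behind them was not given in the sources used here.

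The raw signal was background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, and then taken as log2. A probe was kept when its detection p was under 0.01 on at least 3 of the 6 arrays, which left 16674 probes and removed 28607. A gene silent in scrambled samples was therefore measured only if detected on all 3 knockdown arrays. For lists of such genes, the share of measured members that rose is tilted upward. Gene names came from GEO's platform annotation, which listed 34903 probes, 34885 of them with 1 gene and 18 with several. The other 10378 probes were unnamed. Of the named probes, 34807 matched the RefSeq gene table of assembly GRCm38.p6 by gene number, and 0 symbols differed from it. That table was used for names and for the chromosome a gene lies on, and no coordinates were taken from it. Each gene was represented by the kept probe with the highest mean over all 6 arrays, and an unnamed probe stood for itself, which gave 11782 features, 9569 of them named genes and 2213 unnamed probes. Of 3458 genes with several kept probes, 896 had probes whose changes differed in sign. Among the 1727 such genes that passed the test, 246 did.

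The knockdown group was compared with the scrambled group with limma (lmFit and eBayes), without covariates and with 2-sided tests. A gene was called when its Benjamini-Hochberg adjusted p over all features was under 0.05, and a further count required a change of at least 1.5-fold. Every adjusted p given for a gene is limma's, and every value given as a log2 change is knockdown minus scrambled with its standard error. The 20 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 20 lists. The number of arrays limits the precision, and a permutation of 3 against 3 arrays cannot go below p = 0.1.

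Where a probe was not above background on any array of a group, that group had only a bound, and the fold is written as at least N-fold. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of either the lowest signal among detected probes on that array or the probe's own value, whichever was higher.

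The groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Ncoa3 and Esrrb, the 12 largest rises and the 12 largest falls among named genes past the test whose groups did not overlap, up to 4 called members of each list by size of change, and every member of both pluripotency lists. The alternatives were normexp without negative controls at an offset of 50, no background correction with a floor of 16, cyclic loess, median scaling, the authors' normalized values, no filter or a stricter filter on dim probes, every probe tested, a trended and robust prior, array weights, the replicate number as a block, and each array left out in turn with the probe filter unchanged. Slide as a block was planned but not run, because the sources used here gave no slide or scan date. Median scaling over the kept probes was chosen after seeing the data, as were 5 further gene lists in the closing section.

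The same functions were tested on simulated arrays with 200 changed genes. Of the changed genes, 64.2% were called in the right direction at 1.5-fold, 91.0% at 2-fold and 98.5% at 4-fold, with 15 false calls among 15422 simulated features, which made up 8.15% of the calls, more than the threshold of 0.05 aims at. Simulated arrays with 0 changed genes gave 0 calls. The 200 changed genes were few beside the 46.9% of features called in the real comparison. The rates therefore do not show how normalization and the test behave when so large a share changes. The rates were split by fold only, so none is given for genes not above background in a group.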

Results

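Gene expression was measured in E14 mouse embryonic stem cells 4 days after transfection with an shRNA against Ncoa3, a coactivator of nuclear receptors, or with a scrambled shRNA. There were 3 arrays per group. The number of probes detected above background was 16133, 15720 and 16311 on scrambled replicates 1 to 3, and 16262, 16825 and 17105 on knockdown replicates 1 to 3. Pearson correlations across kept probes ran from 0.994 to 0.996 within a group and from 0.970 to 0.973 between groups. No pair of arrays held identical values.

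The targeted gene was examined first. The single probe named Ncoa3 was not above background on any of the 6 arrays. Its raw intensity was 92.9 ± 6.90 (SD, n = 3) in scrambled samples and 89.9 ± 1.92 (SD, n = 3) in knockdown samples, so no fold is given and the array could not check the knockdown. Esrrb, an orphan nuclear receptor of the naive pluripotency network, is also of interest because the treatment protocol in the labels names an Esrrb shRNA plasmid, while the titles and the series design name Ncoa3. Esrrb fell by 0.62 ± 0.07 (SE) on the log2 scale, or 1.54-fold, from 14.03 ± 0.03 (SD, n = 3) to 13.41 ± 0.09 (SD, n = 3), with a limma adjusted p of 2.55e-04. A further Esrrb probe was not above background on any array.

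The comparison of knockdown with scrambled cells asked which genes differ after the shRNA that the titles name as against Ncoa3. Lefty2 and Lefty1, secreted antagonists of Nodal signalling, fell 41.5-fold and 8.43-fold. Genes of the trophectoderm, the outer lineage of the blastocyst, rose as a group, among them the transcription factor Cdx2 (at least 5.41-fold) and the keratin Krt19 (at least 7.39-fold). The trophectoderm list was called by camera at the preset correlation (adjusted p = 6.03e-08) but not with an estimated correlation (adjusted p = 0.0873). Acta2, the smooth muscle actin, rose at least 17.8-fold on its brightest kept probe. Genes of the naive pluripotency network fell by less, most of them by under 1 on the log2 scale. Across all 11782 features, 2656 were higher and 2868 lower after knockdown, 46.9% in all, and 1900 of them changed at least 1.5-fold, 1097 up and 803 down.

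The share of the called features that were higher depended on the scaling, with 48.1% against 69.1% after median scaling over all probes and 59.8% in the authors' normalized values. Under both scalings 0 of the called features were called with the opposite sign. Median scaling over all probes moved the median change of all features by 0.12 on the log2 scale and left 1589 lower features, and without subtraction of the negative-control background the count at 1.5-fold fell to between 950 and 1024.

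**Figure D1:**
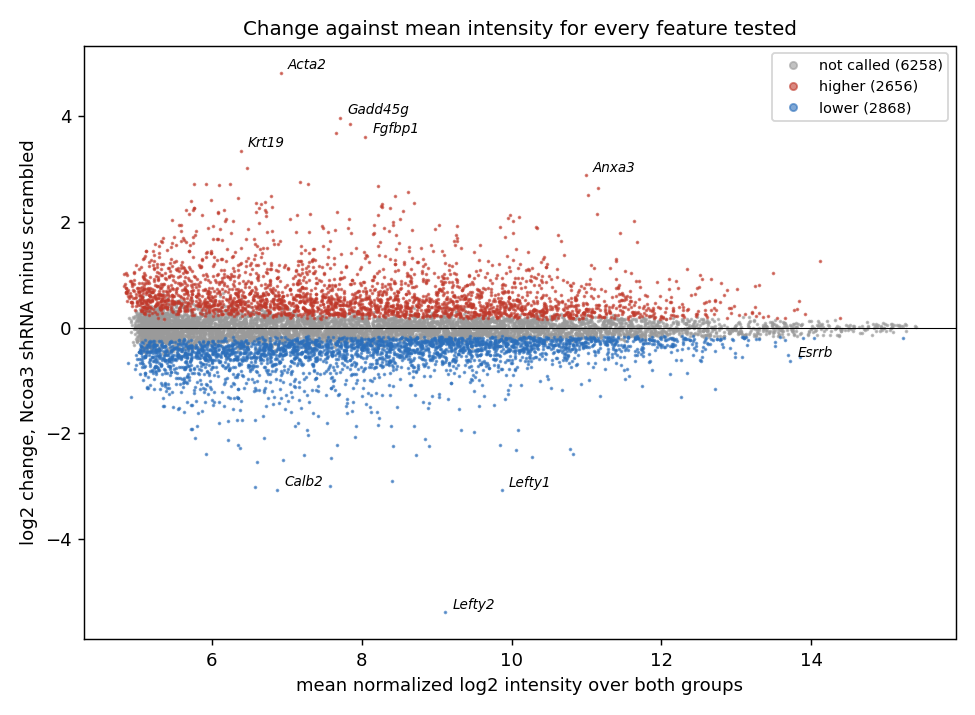
Log2 change (knockdown minus scrambled, vertical axis) of all 11782 features against their mean normalized log2 intensity over both groups (horizontal axis). Red points are the 2656 features called higher, blue points the 2868 called lower, and grey points did not pass the test, and Lefty2 at -5.37 lies farthest below 0. Genes not above background in 1 group, such as Acta2 (at least 17.8-fold higher), are drawn at the fitted difference, for which only a bound was measured.

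Acta2 had the largest rise among named genes. It went from 4.51 ± 0.06 (SD, n = 3), not above background, to 9.32 ± 0.09 (SD, n = 3), with an adjusted p of 9.02e-08. The 4 kept probes of Acta2 had log2 changes from 1.05 to 4.81, and the reported probe had the largest. Gadd45g, a stress and growth arrest gene, rose 15.5-fold, from 5.73 ± 0.20 to 9.69 ± 0.01 (SD, n = 3), with an adjusted p of 7.00e-07. Svop, a synaptic vesicle protein, rose 14.4-fold, and Ms4a10, a membrane protein, 12.8-fold. Fgfbp1, which releases fibroblast growth factors from the matrix, rose 12.2-fold. Anxa3, an annexin, rose 7.34-fold, the costimulatory ligand Cd80 rose 6.68-fold, and the membrane protein Emp3 rose 6.37-fold. The matricellular protein Ccn1 and the guanylate-binding protein Gbp2 were not above background in scrambled samples and rose at least 4.86-fold and 3.88-fold. Log2 changes of the kept probes ran from 2.67 to 3.96 for Gadd45g and from 0.91 to 2.72 for Ccn1. All of these genes had adjusted p-values of 3.07e-06 or less. The rule that picked them required groups that do not overlap, so their higher values on 3 of 3 knockdown arrays are no added evidence. Of all features, 57.8% had groups without overlap, where 10% are expected by chance.

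Lefty2 had the largest fall, from 11.80 ± 0.04 to 6.42 ± 0.06 (SD, n = 3), a log2 change of -5.37 ± 0.06 (SE) with an adjusted p of 2.93e-08. Lefty1 fell by 3.08 ± 0.08 (SE), with an adjusted p of 7.00e-07. The calcium-binding protein Calb2 fell 8.33-fold, the receptor Gpr83 7.96-fold and the myosin light chain Myl4 7.49-fold. The 2 kept probes of Calb2 had log2 changes of -3.06 and -1.60. Falls between 5.29-fold and 5.82-fold were measured for Hopx, a homeodomain-only protein, Nccrp1, the homeobox gene Nkx6-3, the secreted Wnt antagonist Sfrp1, the aspartic protease Napsa and the IgG receptor Fcgrt. The amino acid transporter Slc38a5 was not above background after knockdown and fell at least 4.13-fold. Each had an adjusted p of 6.82e-06 or less, and was lower on 3 of 3 knockdown arrays than on any scrambled array, as the rule required.

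**Figure D2:**
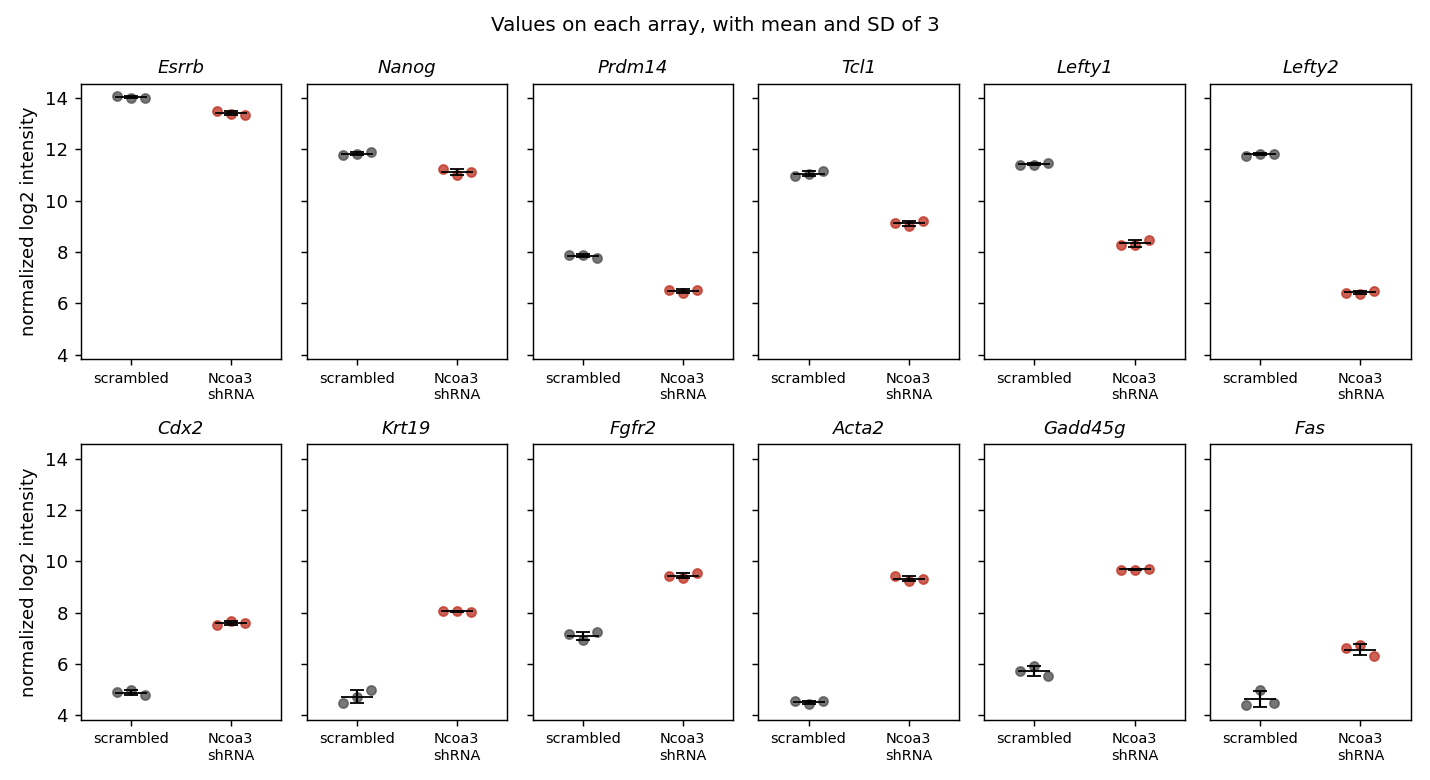
Normalized log2 intensity (vertical axis) of 12 genes on each of the 6 arrays, with scrambled samples in grey and knockdown samples in red. Horizontal bars and whiskers give the mean and SD of 3 arrays, such as 11.80 and 6.42 for the means of Lefty2. In each panel the groups do not overlap, which held for 57.8% of all features.

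Of 25 measured members of the naive pluripotency network, 16 fell, 4 rose and 5 did not pass the test, and the counts were the same when adjusted over the list alone. The largest falls were those of Tcl1, a coactivator of Akt, at -1.94 ± 0.08 (SE) and of the transcriptional regulator Prdm14 at -1.36 ± 0.07. Fgf4 fell by 1.06, Mybl2 by 0.98, Tbx3 by 0.85, Rarg by 0.76 and Nanog by 0.71. The factors Klf2, Tfcp2l1, Klf4, Zfp42 and Nr5a2 fell by 0.64, 0.62, 0.52, 0.50 and 0.41. Of the smaller falls, Dppa5a at -0.20 was not called without scrambled replicate 2 (-0.16) or 3 (-0.22) or without knockdown replicate 1 (-0.20), 2 (-0.23) or 3 (-0.185), nor with cyclic loess, median scaling over all probes or no filter on dim probes. Sox15 at -0.31 was not called without scrambled replicate 3 (-0.26) or knockdown replicate 3 (-0.25), after median scaling over all probes or in the authors' values. Members that rose were Dppa3 at 0.84, Tfap2c at 0.69, and Aire and Fbxo15 at 0.36 each. Klf5, Kit, Gbx2, Pecam1 and Zscan10 had log2 changes from -0.11 to 0.16 and did not pass the test. Of these, Zscan10 was called higher without scrambled replicate 1 (0.22, adjusted p = 0.0391) and in the authors' values (0.23, adjusted p = 0.00427), among other settings. Pecam1 was called lower with every probe tested (-0.16, adjusted p = 0.0253). The median change was -0.42 and the list was called lower by camera (adjusted p = 0.00659), with an adjusted p of 0.101 with an estimated correlation. Nr0b1 was not above background on any array.

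The pluripotency factors shared with the primed state moved less evenly. Pou5f1, the core factor also called Oct4, fell by 0.30 ± 0.07 (SE), from 12.77 ± 0.09 to 12.47 ± 0.04 (SD, n = 3), and Sox2 fell by 0.43 ± 0.10 (SE). The Nodal coreceptor Tdgf1 fell by 0.70, whereas Dnmt3l, a cofactor of DNA methylation, rose by 1.04 and Utf1 by 0.32. Nodal itself had a log2 change of -0.02, Gdf3 of -0.09 and Sall4 of 0.13, none past the test. The representative Lin28a probe had a change of -0.40 that did not pass the test after median scaling over all probes, and its 4 kept probes ran from -0.77 to 0.63 and differ in sign, and the Sall4 probes also differ in sign, from -0.37 to 0.13. L1td1 at -0.28 was not called without scrambled replicate 3 (-0.21) or without knockdown replicate 1 (-0.29), 2 (-0.26) or 3 (-0.30), after median scaling over all probes, in the authors' values or without the filter on dim probes. Tex19.1 at -0.32 was not called after median scaling over all probes (-0.18). Lefty1 and Lefty2 belong to this list and had its largest falls. In total 9 of 19 measured members fell and 2 rose, also when adjusted over the list alone, with a median of -0.24. The list was not called (adjusted p = 0.131, and adjusted p = 0.286 with an estimated correlation).

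Of 19 measured members of the trophectoderm list, 17 rose and 2 fell, the same counts when adjusted over the list alone, with a median log2 change of 1.26. The median was 0.72 without background correction and 0.78 in the authors' normalized values. A further 6 of the 25 trophectoderm genes on the array did not pass the detection filter. Beside Krt19 and Cdx2, the fetal growth factor Igf2 rose 6.23-fold and the receptor Fgfr2 5.05-fold, from 7.10 ± 0.16 to 9.44 ± 0.09 (SD, n = 3). The 2 kept probes of Fgfr2 had log2 changes of 1.103 and 2.335. The members that fell, named after their values were seen, were the imprinted gene Phlda2 at -0.92 and Tead4, a factor upstream of Cdx2, at -0.39. Elf5 and Hand1, also trophoblast markers, and Eomes, a factor of early trophectoderm and of the primitive streak, were not above background on 3 or more arrays. The list was called higher by camera (adjusted p = 6.03e-08), with an adjusted p of 0.0873 with an estimated correlation. Fibroblast matrix genes gave no matching signal, since none of Col1a1, Col1a2, Col3a1, Lum, Dcn and Postn was detected on more than 1 knockdown array.

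Genes of the primed epiblast, the state that follows naive pluripotency, rose in 12 of 17 measured cases and fell in 3, with a median of 0.45. Sox11 rose 3.01-fold, Pou3f1 2.16-fold and Sox4 1.94-fold. The members that fell were Fgf15, at least 1.77-fold lower and not above background after knockdown, and, named after their values were seen, Tead2 at -0.52 and Etv4 at -0.18. Of 16 measured genes of primitive and visceral endoderm, 10 rose and 3 fell, with 11 rising when adjusted over the list alone. A further 15 of the 31 endoderm genes on the array did not pass the detection filter, nor did 9 of 26 primed epiblast genes. The endoderm median was 0.515, and 0.13 without the filter on dim probes. The endocytic receptor Lrp2 rose 5.00-fold, the plasminogen activator Plat 4.82-fold, and the basement membrane genes Sparc and Col4a2 2.58-fold and 2.08-fold. Those that fell, named after their values were seen, were Amn at -0.59, Apoe at -0.58 and Lama1 at -0.33, while Gata4 and Sox17 were not above background on any array. The lists had camera adjusted p-values of 0.00659 and 0.00717, and each had an adjusted p of 0.101 with an estimated correlation.

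**Figure D3:**
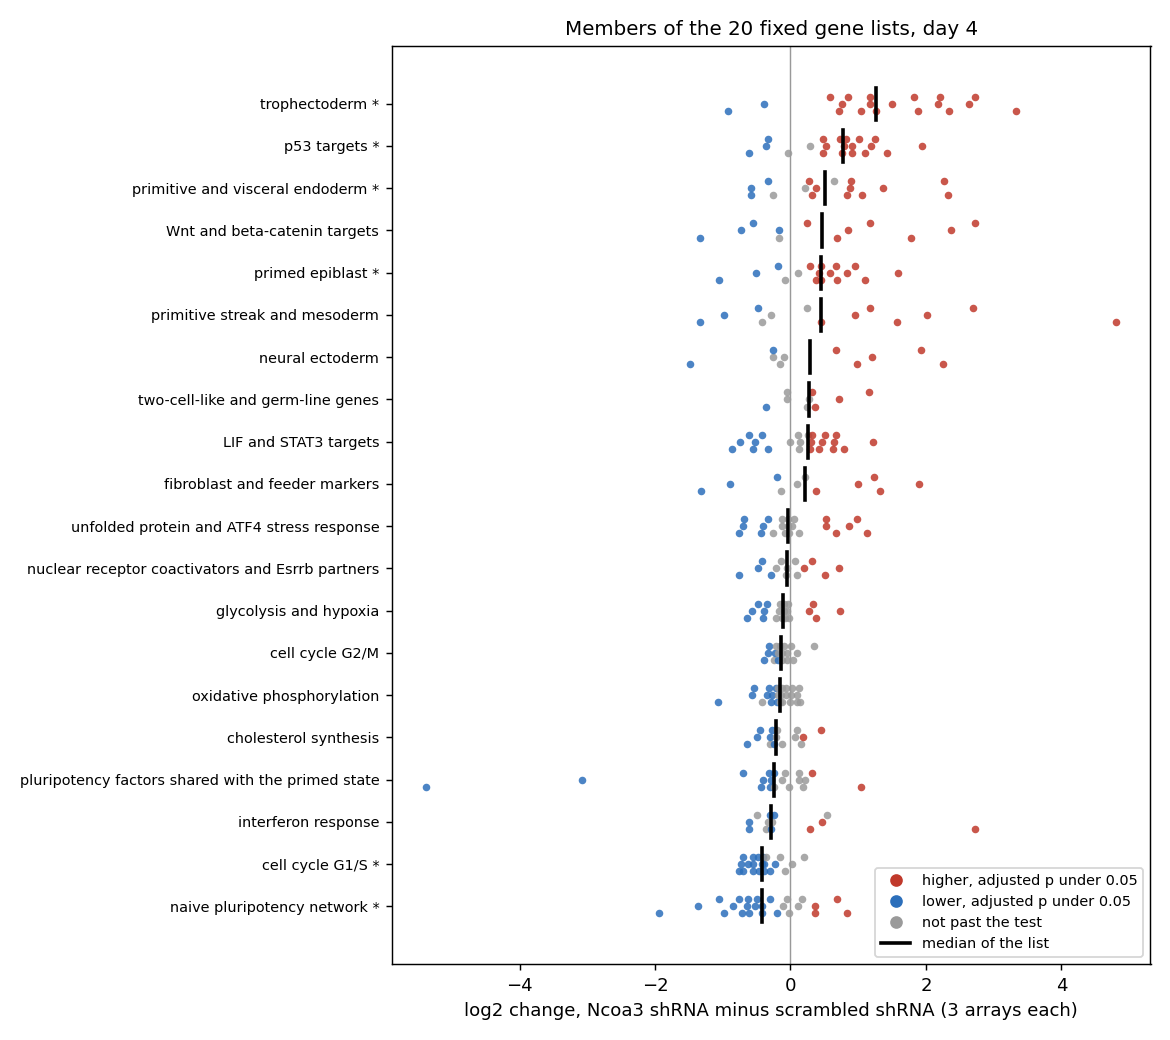
Log2 change (knockdown minus scrambled, horizontal axis) of each measured member of the 20 gene lists, 1 row per list ordered by median, which is drawn as a black bar. Red and blue points passed the test, grey points did not, and an asterisk marks the 6 lists called by camera at the preset correlation, from trophectoderm (median 1.26) to the naive pluripotency network (median -0.42).

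Targets of p53, the DNA damage response factor, rose in 15 of 20 measured cases and fell in 3, also when adjusted over the list alone, with a median of 0.77. The death receptor Fas, not above background in scrambled samples, rose at least 2.62-fold. The 2 kept probes of Fas had log2 changes of 0.96 and 1.94. Ddit4, an inhibitor of mTORC1, rose 2.68-fold, the RNA-binding protein Zmat3 2.36-fold and the apoptosis gene Bbc3 2.27-fold. The members that fell, named after their values were seen, were Sesn1 at -0.62, Tnfrsf10b at -0.37 and Ei24 at -0.33. The 3 kept probes of Tnfrsf10b differ in sign, from -0.37 to 0.85. Genes of the G1/S transition fell in 16 of 21 measured cases with 0 rising, or 17 falling and 1 rising when adjusted over the list alone, and their median was -0.42. The replication factors Cdc45 and Gins2 fell by 0.75 and 0.71, the histone chaperone subunit Chaf1b by 0.73 and the cyclin Ccne1 by 0.71. Both lists had a camera adjusted p of 2.38e-05, and an adjusted p of 0.0709 with an estimated correlation. Genes of G2/M fell in 5 of 18 cases with 0 rising, among them Aurka at -0.39 and Top2a at -0.31, and that list was not called (adjusted p = 0.117, and adjusted p = 0.247 with an estimated correlation). Of the 5, Plk1 at -0.24 was not called without scrambled replicate 2 (-0.24) or 3 (-0.22), without knockdown replicate 1 (-0.19) or 2 (-0.22), after median scaling over all probes or without the filter on dim probes. Nusap1 at -0.32 was not called without scrambled replicate 3 (-0.26) or knockdown replicate 2 (-0.26) or after median scaling over all probes.

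The other lineage lists were not called. Of 31 genes of the primitive streak and mesoderm list on the array, 18 did not pass the detection filter. Of the 13 measured members, 7 rose and 3 fell, with a median of 0.45, or 0.41 with dim genes at their bounds. Those with the largest rises were genes of contractile and matrix cells, Acta2, Ccn1, Ccn2 at 4.03-fold and Tagln at least 1.82-fold. Those that fell, named after their values were seen, were Bmp4 at -0.99, Evx1 at -0.48 and Cdx1, at least 1.93-fold lower on its representative probe. The size of the Cdx1 fall rested on the choice of probe, since its 2 kept probes had log2 changes of -1.34 and -0.21. The second probe took the place of the first without scrambled replicate 2 (log2 change -0.22) or 3 (-0.15), and neither value passed the test. Cdx1 was also not called with cyclic loess, median scaling over all probes or the authors' values. The list had an adjusted p of 0.0683, its median was -0.0398 without the filter on dim probes and 0.0171 on features detected on all 6 arrays (adjusted p = 0.748), and it was called without scrambled replicate 2 (0.0373) or 3 (0.0246). Neural ectoderm genes rose in 5 of 10 cases and fell in 2 (median 0.29, adjusted p = 0.208), with Nes 4.76-fold and Stmn2 3.82-fold higher and the microtubule gene Mapt 2.78-fold lower. The 2 kept probes of Nes had log2 changes of 0.99 and 2.25, and those of Mapt -1.48 and -0.54. A further 15 of the 25 neural genes on the array did not pass the detection filter. Genes of the 2-cell-like state and the germ line rose in 4 of 9 cases and fell in 1, with Zscan4c 2.24-fold higher (median 0.28, adjusted p = 0.160). The 1 that fell, Dazl at -0.37, was not called without scrambled replicate 2 (log2 change -0.34, adjusted p = 0.0532) or after median scaling over all probes (log2 change -0.25, adjusted p = 0.0604). The median of the neural list was 0.05 with dim genes at their bounds and -0.17 on features detected on all 6 arrays.

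Lists of signalling and stress genes moved in both directions. Among targets of LIF and STAT3, 11 of 23 rose, such as Junb at 1.73-fold and Fos at least 1.85-fold, and 7 fell, such as Bcl3 at -0.87 and Mras at -0.75 (median 0.25, adjusted p = 0.160). Among Wnt targets, 7 of 12 rose, with Sp5 5.16-fold and Sox9 3.43-fold higher, and 4 fell (median 0.46, adjusted p = 0.117). The Wnt median was 0.33 with dim genes at their bounds and -0.17 on features detected on all 6 arrays. The interferon list had 3 members higher, Gbp2 and Ifitm3 (1.39-fold) and, named after its value was seen, Irf1 at 0.29, and 5 lower, among them Stat2 at -0.62 and Parp14 at -0.61. Its median was -0.29 and its mean 0.04, so they differ in sign, and its adjusted p was 0.584. Unfolded protein and ATF4 genes rose in 6 and fell in 6 of 22 cases, with Ddit3 1.98-fold higher, Herpud1 1.82-fold higher, Atf3 at least 1.38-fold higher and the mitochondrial enzyme Shmt2 at -0.75. The median of that list was -0.04, its mean 0.04 and its adjusted p 0.940, and its median was above 0 after median scaling over all probes and in the authors' values.

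No member of the oxidative phosphorylation list rose and 9 of 25 fell, 8 when adjusted over the list alone, including the coactivator Ppargc1b at -1.07, Sdhc at -0.57, Cyc1 at -0.54 and Ndufv1 at -0.34. The list's median was -0.15 with an adjusted p of 0.0586, and it was called without scrambled replicate 1 (0.0223), under each of the alternative background corrections and scalings, with every probe tested, without the filter on dim probes, and with array weights or a trended prior. In glycolysis and hypoxia 4 of 20 rose, led by the glucose transporter Slc2a1 at 1.67-fold, and 6 fell, among them Aldoc at -0.65 and Hk1 at -0.57 (median -0.11, adjusted p = 0.246). In cholesterol synthesis 2 of 15 rose, Sqle at 1.37-fold and, named after its value was seen, Srebf2 at 0.19 (its 2 probes differ in sign), and 6 fell, 7 when adjusted over the list alone, among them Insig1 at -0.65 and Pmvk at -0.50 (median -0.22, adjusted p = 0.236).

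Among nuclear receptor coactivators and partners of Esrrb, 4 of 14 measured genes rose and 4 fell (median -0.06, adjusted p = 0.925). This median was -0.10 without scrambled replicate 1 and 0.04, above 0, after median scaling over all probes. The retinoid receptor Rxra rose 1.65-fold and Esrra 1.42-fold, while Rarg fell by 0.76 and Rara by 0.48. The paralogs Ncoa1 and Ncoa2 were not above background on any array. In the fibroblast and feeder list 5 of 11 measured members rose and 3 fell (median 0.21, adjusted p = 0.192). The median of this list was 0.0452 without the filter on dim probes, 0.0848 without background correction and 0.08985 with normexp at an offset of 50. Vim, an intermediate filament gene, rose 3.71-fold, Timp3 2.50-fold and Anxa1 at least 1.53-fold, whereas the surface glycoprotein Thy1 fell by 1.32. Counts adjusted over the list alone were the same for the lineage, signalling, stress and metabolic lists except where given and except the interferon list, with 4 higher and 7 lower. With an estimated correlation none of the 20 lists was called. Of the 6 lists called at the preset 0.01, only trophectoderm had a higher estimate, 0.072. The estimates were 0.0065 for the naive network, -0.027 for p53 targets and -0.027 for G1/S. Those of primed epiblast and endoderm were -0.044 and -0.038. The loss of these other calls therefore does not show correlation among members above the preset, and its cause was not tested.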

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

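The alternatives were planned before the data were examined, except median scaling over the kept probes, which was chosen after seeing the data. The counts of higher and lower features stayed within 1.5 times of the reported ones, except for 1589 lower features after median scaling over all probes. The count at 1.5-fold was 1024 with normexp at an offset of 50, 950 without background correction and 974 in the authors' normalized values. In those settings 36, 42 and 48 of 118 called named genes had changes over 1.5 times smaller, such as Cdx2 at 1.43 in the authors' values. Those settings differ from the reported fit in background handling, and some also in offset or scaling, so the part of each cannot be told apart. Features detected on all 6 arrays cannot include probes at background in a group, so Acta2, Cdx2 and Krt19 had no value there. A gene could still enter through another probe detected on all 6 arrays. The Ncoa3 probe was not above background on any array, so no setting gave it a fold, and slide as a block was not run. Across arrays left out singly, 82.7% to 87.1% of the called features were called again with the same sign.

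The same 6 lists were called under every setting at the preset correlation, and 0 with an estimated correlation, where the medians 1.26, 0.77, 0.52, 0.45, -0.42 (naive) and -0.42 (G1/S) lost their call. With normexp at an offset of 50, without background correction and in the authors' values, some medians of called lists were smaller. They were 0.72 to 0.78 for trophectoderm, 0.28 to 0.31 for primed epiblast and 0.27 to 0.29 for endoderm. The endoderm median was 0.13 without the dim-probe filter. Without that filter 12 lists were called, and 10 after median scaling over the kept probes. Oxidative phosphorylation was called at medians of -0.14 (normexp at an offset of 50), -0.14 (no correction), -0.13 (cyclic loess), -0.0754 (median scaling), -0.0896 (authors' values), -0.14 (no filter), -0.17 (every probe), -0.15 (trended prior), -0.16 (array weights) and -0.23 (kept-probe scaling). It ranged from -0.21 to -0.13 with an array left out. The mesoderm list ranged from 0.39 to 0.50 with an array left out, was called at 0.45 with every probe and 0.46 with kept-probe scaling, and reversed to -0.0398 without the filter. Without the filter, shared pluripotency (-0.12), 2-cell-like (0.0452), LIF (0.27), Wnt (0.0772) and G2/M (-0.13) lists were called. Shared pluripotency was also called after median scaling over all probes (-0.0895), and Wnt (0.46) and G2/M (-0.21) after kept-probe scaling. On features detected on all arrays the neural and Wnt medians reversed to -0.17 each, and the mesoderm median was 0.0171. The unfolded protein median reversed to 0.0489 after median scaling and 0.0291 in the authors' values, and the coactivator median to 0.0423 after median scaling. The cause of these shifts was not tested.

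Of 2343 values of the 131 named genes under the alternatives, 2269 kept their direction and call, 38 lost the call, 26 gained it and 10 reversed. Among the genes that gained a call were Zfp281 and Zscan10, each called higher under several settings. Calls were lost by Dppa5a in 9 settings (the replicate block among them, adjusted p = 0.0504), L1td1 in 7, Plk1 in 6, Cdx1 in 5, Sox15 in 4, Nusap1 in 3, Dazl in 2, and Lin28a and Tex19.1 in 1 each. The reversals were of genes that had not passed the test in the reported fit: the log2 change of Kit (0.0318, 0.11 and 0.0826 with cyclic loess, median scaling and the authors' values, and 0.0434 without knockdown replicate 2), Nodal (0.00639, 0.0480 and 0.0309 in those 3 settings), Pecam1 (0.10 with median scaling and 0.0431 in the authors' values) and Sall4 (-0.12 with every probe, where it passed the test as lower, adjusted p = 0.0112). Without knockdown replicate 3 the log2 change of Kit was -0.0782, with its reported sign. Replicate numbers did not pair the samples, with correlations of -0.004, -0.006 and 0.02 between same-numbered deviations, and not every sample correlated best with its own number. The replicate block gave 2511 higher and 2622 lower features, 1903 at 1.5-fold and 6 lists.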

Other observations

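The tests of fibroblasts, of whole chromosomes, of a lower share of undifferentiated cells, of quantile normalization as the whole cause, and of the 5 further gene groups were chosen only after the result was seen.

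Most members of a list of actin and contractile genes rose. The list also held genes that are not filament or contractile proteins, among them Ccn1, Ccn2, Amotl2 and Ankrd1. It was put together once the data had been seen. Of its 23 measured members, 20 rose and 1, the transcription factor Srf, fell (-0.32). Without the 8 members whose values had been seen, 12 of 15 rose, among them the focal adhesion gene Zyx at 1.63, the calponin Cnn2 at 1.27, the myosin Myh9 at 1.13 and the vinculin gene Vcl at 0.58. Their median of 0.58 lay at the 100th percentile of 10000 random lists matched on mean expression. Such random lists, here and below, treat genes as independent. The percentiles therefore take no account of members that move together or of the 3 arrays per group. Amotl2 rose by 1.86, while Ankrd1 and Actb had log2 changes of 0.005 and 0.08 and did not pass the test. Imprinted genes were also more often higher: of 33 measured, 16 rose and 3 fell. Leaving out the 4 seen before, the median of 29 genes was 0.23, at the 99.9th percentile, with Nnat at 1.67, Peg3 at 1.28 and Cdkn1c at 0.77 higher and Slc22a18 at -1.14 lower, although the 2 probes of Slc22a18 differ in sign. These groups may each have moved as a unit, a hypothesis found and tested on the same arrays.

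Of 8 measured targets of BMP signalling, Gata2, Gata3, Msx1 and Tfap2a had been seen to rise before the list was made. The other 4 also rose, Id2 at 1.80, Id1 at 1.08, Smad6 at 0.97 and Id3 at 0.35, with a median of 1.03 (percentile 99.95), while the ligand Bmp4 fell by 0.99. A percentile from only 4 genes decides little. Heat shock genes, in contrast, rose in 1 and fell in 1 of 10 cases, with a median of -0.06 at the 34.2nd percentile. The fall of Lefty1 and Lefty2 raised the hypothesis of lower Nodal signalling to its other targets. The 6 other measured members of that list include parts of the pathway, such as Nodal itself and its coreceptor Tdgf1. Their median was -0.05, at the 45.5th percentile, with Tdgf1 at -0.70 and Foxh1 at -0.50 lower and Skil at 0.54 and Ski at 0.31 higher. With such members, and with members moving both ways, this median does not decide whether Nodal signalling changed.

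Almost every 2nd measured feature was called, which invites a technical explanation. Scaling by the median of the kept probes, without quantile normalization, still called 48.8% of features, which argues against quantile normalization as the whole cause, although median scaling over all probes called 76.8% of the same features with the same sign, a share that leaves its part in single calls open. No autosome, nor the X, had a median change above 0.0707 in size, which argues against the gain or loss of 1 of these chromosomes in most cells. The ranges of mean raw signal overlapped, with 2 arrays inside the range of the other group. The values were 390.2, 428.9 and 400 on knockdown arrays and 389.9, 387 and 395.3 on scrambled arrays. The overlap rests on knockdown replicate 1, and with 3 arrays per group it cannot exclude brighter knockdown arrays. A batch that matched the groups, an effect of the shRNA on other transcripts and the knockdown itself remain open, since no scan date, second shRNA or Ncoa3 level was at hand. An shRNA against Esrrb, which the treatment protocol names in place of Ncoa3, also stays open. The fall of Esrrb does not decide this.

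The rise of trophectoderm genes could come from other cells or from dim probes. None of 6 abundant fibroblast matrix genes (0) was detected on at least 2 of 3 knockdown arrays, which argues against fibroblasts. Of the 17 members that rose, 11 were detected on at least 2 of 3 scrambled arrays, with a median change of 1.49, which argues against probes lifted from the background. A trophoblast-like change of some cells stays open as a hypothesis and was not tested.

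The fall of naive pluripotency genes might reflect only a smaller share of undifferentiated cells. The log2 changes of the members had an SD 8.80 times their median standard error, but this ratio was at least 2.82 in each of the 20 lists, so the test could not have come out otherwise and decides nothing. Cells that express none of the members would dilute every member alike and raise none, but 4 members rose, Dppa3, Tfap2c, Aire and Fbxo15, each called in every alternative as well. This argues against dilution by such cells as the whole cause. Dilution by cells that express some of the members, and a change within the cells, stay open.

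Each 3 against 3 regrouping of the 6 arrays was also fitted. The real grouping called 5524 features, 1900 of them at 1.5-fold, and 6 lists, and the highest of the other 9 groupings called 0, 0 and 4. Only 1 of the 10 splits, the real one, reached each of these results, but 10 splits are too few for a share under 0.05. The other groupings mix arrays of both groups, so the group difference adds to their spread and their 0 gene calls decide little. They called 3, 2, 2, 1, 0, 3, 3, 3 and 4 lists, so lists were also called at the preset correlation in mixed groupings. Each mixed grouping keeps a part of the group difference, so these list calls are not a rate of false calls.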
